A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

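Transcript levels of 3 Saccharomyces cerevisiae strains were measured on 6 dual-colour arrays. Per the labels, total RNA of one strain was labelled for Cy5 in channel 1 and that of another for Cy3 in channel 2 with the Genisphere 3DNA system. In that system dye-bearing DNA dendrimers bind a tag on the cDNA. The strains are S288C wt, ssy1KO and ssy1T9, and they form a closed loop: each of the 3 pairs of strains was hybridised on 2 arrays with the dyes exchanged. Within a pair of a mutant and wt, replicate 1 is the array with wt in Cy5 and replicate 2 the array with wt in Cy3; within the pair of mutants, replicate 1 has ssy1T9 in Cy5. These numbers only name the arrays and pair none of them across groups.

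The values analysed are the deposited value table of the 6 arrays, 1 log ratio per spot and array. Scanner, image software, background correction, normalization, log base and the direction of the ratio are not given in the sources used here. The values were taken as log2 ratios, and every fold in the text rests on that assumption; with another base the folds would differ, and so would the counts of at least 2-fold, the test against a 1.2-fold change and the bound for an extra copy near URA3. Directions and tests against no change do not depend on the base. The direction was taken as Cy5 over Cy3 by a rule set before the data were examined: the sign in which SSY1 lies lower in ssy1KO on all 4 arrays that hold that strain. The direction is therefore likely, not stated. The deposited log2 columns were not centred: over genes, the median was -0.58 for wt over ssy1KO, -0.51 for wt over ssy1T9, -0.08 for ssy1T9 over wt, -0.35 for ssy1KO over wt, -0.39 for ssy1T9 over ssy1KO and -0.33 for ssy1KO over ssy1T9.

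The table holds 7744 rows with 0 missing values. Of these, 6116 rows have 1 gene symbol in the platform annotation, 0 have several and 1628 are unnamed here. Symbols were updated through the gene identifier to the R64 reference names, which matched 6111 of the named rows; the other 5 kept the annotation's symbol. Spots of one gene were averaged per array, giving 5711 genes, 5678 of them with 1 spot and 33 with more. Unnamed rows were left out of the comparisons and tested apart. The reference was otherwise used only to find which genes neighbour each other.

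Each array was centred on its median over genes. A linear model with a gene-specific dye intercept and coefficients for ssy1KO and ssy1T9 relative to wt was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual and 20.7 prior degrees of freedom). The comparison of ssy1KO with ssy1T9 is a contrast of the same fit and is also the test of whether the effects of the alleles differ. Genes with a Benjamini-Hochberg adjusted p under 0.05 in a two-sided test are called higher or lower. Errors are standard errors (SE) of the fit over 6 arrays unless stated. The labels do not say whether the arrays of a pair came from separate cultures or extracts, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision: the median SE was 0.08 on the log2 scale, for a 95% confidence interval of 0.166 to either side, or 1.12-fold. The spread between 33 spots of the same gene, measured for 12 genes, had a median SD over arrays of 0.113 to 0.261.

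The 28 gene lists were fixed from textbook yeast physiology before the data were examined. Each was tested against all other genes with limma's camera (preset inter-gene correlation of 0.01, and again with an estimated correlation) and on its own with fry, adjusted over the 28 lists within a comparison. Camera adjusted p-values are with the preset correlation unless the estimated one is named. With the preset correlation camera takes its degrees of freedom from the number of genes, and with an estimated one from the 3 residual degrees of freedom. A list that passes only with the preset correlation may therefore lose its call through the few arrays and not through correlation between its members. Members past the threshold were counted after adjustment over all genes and adjusted over the list alone. The genes named are, by a rule of the same time, SSY1, all measured genes of the sensor pathway and of the permeases it controls, the 10 largest rises and falls per mutant against wt among called genes whose own arrays of that pair go one way, the 5 largest of each between the mutants, and up to 4 genes per list by size of change. Genes outside that rule are said to be chosen after their values were seen. Because both mutants are compared with the same wt, the likeness of their effects was also computed for 100 simulated data sets without effects, and so was the overlap of calls and, added after the data were seen, of lists as long as the real ones.

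The fit was tested on simulated data for the 5711 genes with 200 changed in both mutants. In all simulations the noise was normal and drawn independently for each gene and array, so no error shared between arrays was included. For ssy1KO against wt and for ssy1T9 against wt, 100% of the changes of 0.5 and 100% of those of 1 on the log2 scale were called, with 11 and 7 false calls. Between the mutants, where nothing was changed, 0 genes were called. Alternatives tried were no dye intercept, no centring, arrays scaled to one spread, each spot row on its own, dye-swapped arrays averaged before the fit, each comparison from its own 2 arrays, robust eBayes, a test against a 1.2-fold change, each array left out in turn and, added after the data were seen, centring of 16 runs of consecutive rows apart. Figures were drawn with matplotlib. Spot intensities were not analysed here, so faint and bright spots are not told apart, and cross-hybridisation between near-identical genes is not excluded.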

Results

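Transcript levels were compared between 3 strains of budding yeast: wt, ssy1KO and ssy1T9. The array titles name S288C, a common laboratory background, beside wt only, and give no background for the mutants. SSY1 encodes the plasma membrane amino acid sensor that works with Ptr3 and Ssy5 (the SPS sensor). On sensing external amino acids it releases the transcription factors Stp1 and Stp2, which induce amino acid permease genes. By its name ssy1KO lacks the gene, and the series title presents a natural variant that changes expression; the labels describe ssy1T9 no further. Each of the 3 pairs of strains was hybridised on 2 arrays in opposite dye orientations, 6 arrays in all, and 5711 genes were measured on every array. Arrays are named by their pair, as KO/wt, T9/wt or T9/KO, with number 1 for wt in Cy5 or, in T9/KO, ssy1T9 in Cy5. The design asks how each allele changes the transcriptome and how far their effects differ. Values are log2 ratios with the base assumed and the direction likely, as set out with the processing.

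SSY1 itself was 2.72-fold lower in ssy1KO than in wt (log2 -1.44, SE 0.09, adjusted p = 1.5e-12). It read -1.65 and -1.10 on the KO/wt arrays, and -1.86 and -1.87 in ssy1KO over ssy1T9 on the T9/KO arrays. These readings set the direction of the ratio, so they are no separate check of the labels, and whether the probe lies within the deleted part is not given in the sources used here. In ssy1T9 the SSY1 transcript was 1.28-fold higher than in wt (log2 0.36, SE 0.09, adjusted p = 0.00302), with 0.22 and 0.36 on the T9/wt arrays. From these 2 arrays alone the difference was 0.29 and did not pass (adjusted p = 0.0896), nor did it pass a test against a 1.2-fold change (adjusted p = 1).

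In ssy1KO, all 9 measured permease genes controlled by the sensor fell against wt. The branched-chain amino acid permease genes BAP3 and BAP2 were 9.55-fold and 6.42-fold lower. The tyrosine and tryptophan permease genes TAT1 and TAT2 were 8.80-fold and 3.79-fold lower, the glutamine permease gene GNP1 4.81-fold lower and the peptide transporter gene PTR2 4.63-fold lower. The methionine permease gene MUP1 fell by 1.75 on the log2 scale, the dicarboxylic amino acid permease gene DIP5 by 1.52 and the broad-range permease gene AGP1 by 0.73. SEs of these 9 genes lay between 0.077 for PTR2 and 0.093 for TAT1. CHA1, encoding the catabolic serine and threonine deaminase, was 9.59-fold lower (SE 0.09). The largest rises were in genes for use of other nitrogen sources: PUT1, encoding proline oxidase, was 16.04-fold higher (SE 0.08), the general amino acid permease gene GAP1 rose to a log2 of 3.46 (SE 0.08), and the allantoin pathway gene DAL3 was 9.14-fold higher (SE 0.09).

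By limma, 1386 of 5711 genes differed in ssy1KO against wt, 789 higher and 597 lower, with 53 and 24 of them at least 2-fold. Among the called genes 90.8% had one sign on both KO/wt arrays, against 45.5% of the genes not called. Both arrays are part of the fit that made the calls, so this agreement is partly built in. As Cy5 over Cy3 these arrays correlated across genes with r = -0.55 (Spearman -0.28), where a shared effect has a negative sign. Without centring, the median of all genes lay at 0.16 and the split was 1807 higher and 155 lower (92.1% higher, against 56.9%), so directions of small changes are relative to the typical gene. Without KO/wt array 1, 626 genes were called.

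**Figure D1:**
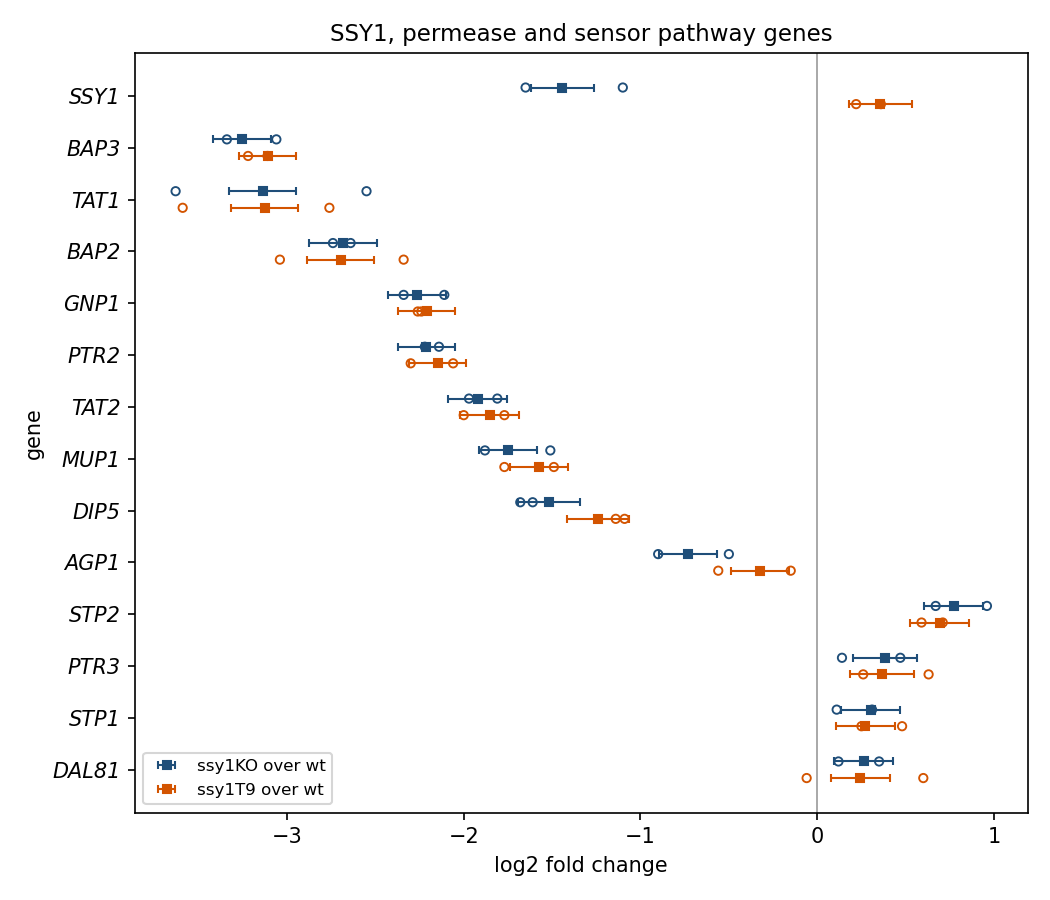
Log2 fold change of ssy1KO (blue) and ssy1T9 (orange) over wt for SSY1, the 9 permease genes controlled by the sensor and 4 genes of its pathway. The 4 are the other pathway genes called higher in both mutants, and the 7 that did not pass are not drawn. Squares are fitted values over 6 arrays with 95% confidence intervals and open circles the 2 arrays of the pair; all 9 permease genes lie below 0 in both mutants, while SSY1 lies at -1.44 in ssy1KO and at 0.36 in ssy1T9.

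Several groups of genes fixed beforehand stood apart from all other genes in ssy1KO. The permease list was lower (median log2 -2.21, camera adjusted p = 2.4e-26), with 9 of 9 members lower over all genes and 9 adjusted over the list alone. Of 27 nitrogen catabolite repressed genes, which preferred nitrogen sources hold down, 16 rose and 1 fell, and 16 and 2 adjusted over the list alone (median 0.47, adjusted p = 1.3e-11). They included the repressor gene DAL80 (log2 2.20) as well as PUT1, GAP1 and DAL3. Of 27 genes of sulphate assimilation and methionine metabolism, 20 rose and 1 fell, with the same counts adjusted over the list alone (median 1.06, adjusted p = 1.8e-23). MET14, encoding adenylylsulphate kinase, rose to 2.40, the sulphite reductase subunit gene MET10 to 2.15, and MET17, encoding homocysteine synthase, to 2.17. Of 24 general stress genes 17 rose and 0 fell, also adjusted over the list alone (median 0.52, adjusted p = 1.5e-11). Among them were the phosphoglucomutase gene PGM2 (1.38), DDR2 (1.17) and the heat shock protein genes HSP42 (1.12) and HSP26 (1.01). With an estimated correlation these 4 lists, and none of the other 24, passed in ssy1KO, each at an adjusted p of 0.035.

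Several amino acid biosynthesis lists also lay higher in ssy1KO under the preset correlation. Of 12 branched-chain genes, 6 rose and 0 fell, also adjusted over the list alone (adjusted p = 1.2e-04; adjusted p = 0.152 with an estimated correlation). LEU2 and LEU1, encoding isopropylmalate dehydrogenase and isomerase, rose to 2.38 and 1.98, and the mitochondrial aminotransferase gene BAT1 to 1.31. Histidine genes rose in 6 of 7 cases, 6 adjusted over the list alone (adjusted p = 3.7e-05; adjusted p = 0.0812 with an estimated correlation), with HIS4 at 0.92. Arginine genes rose in 5 of 8 cases, 6 adjusted over the list alone (adjusted p = 3.7e-05; adjusted p = 0.0812 with an estimated correlation), with ARG4, encoding argininosuccinate lyase, at 1.36. Of 13 glutamate, proline and asparagine genes 7 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0018; adjusted p = 0.162 with an estimated correlation). The NADP-dependent glutamate dehydrogenase gene GDH1 rose to 2.23 and the peroxisomal citrate synthase gene CIT2 to 1.15. Beside these groups, genes often deleted in laboratory strains were higher as well: 6 of 8 such markers rose, also adjusted over the list alone (adjusted p = 1.7e-09; adjusted p = 0.152 with an estimated correlation). LEU2, MET17, HIS3, LYS2 and CAN1 were among them in both mutants, and the first 4 are also members of biosynthesis lists.

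Other groups fell in ssy1KO. Of 17 serine, glycine and threonine genes 7 fell and 3 rose, 8 and 3 adjusted over the list alone (adjusted p = 0.00169; adjusted p = 0.2 with an estimated correlation). The median was -0.20, and -0.05 without centring; beside CHA1, the glycine cleavage genes GCV1 and GCV2 fell by 1.70 and by 0.93. Of 137 cytosolic ribosomal protein genes 100 fell and 0 rose, 109 adjusted over the list alone, with a median of -0.31, and of -0.15 without centring (camera adjusted p = 1.8e-23). The list did not pass with an estimated correlation (adjusted p = 0.2), a test on 3 degrees of freedom. Whether correlation between members or the few arrays cost the call is not told apart. Close paralogs among these genes may share signal on the array. RPL38 and RPP1A fell by 0.48 and by 0.50. Of 22 ribosome biogenesis genes 13 fell, 16 adjusted over the list alone (adjusted p = 2.0e-07; adjusted p = 0.052 with an estimated correlation). Their median was -0.27, and -0.11 without centring, and DBP2, a helicase gene, fell by 0.49. Among the 10 largest falls of single genes were also the oligopeptide transporter gene OPT1 (log2 -1.87), the acid phosphatase gene PHO3 (-1.85) and the cytosolic malate dehydrogenase gene MDH2 (-1.85). Among the 10 largest rises were also the GATA factor gene GAT1 (2.22) and RGI1 (2.16).

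**Figure D2:**
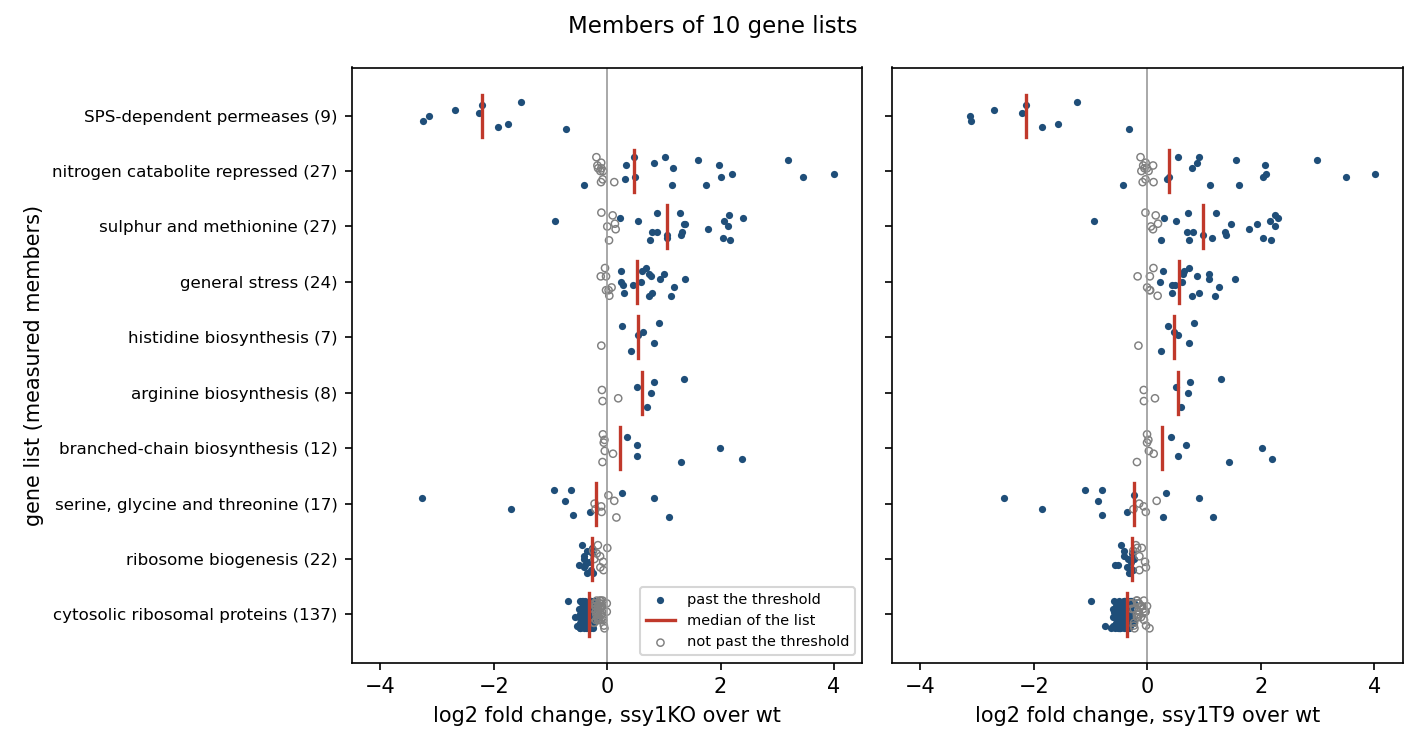
Log2 fold change over wt of each measured member of 10 gene lists, in ssy1KO (left) and ssy1T9 (right). Filled points passed the threshold over all genes, open ones did not, vertical scatter within a list only separates points, and red lines mark list medians, such as -2.21 and -2.15 for the permeases and -0.31 and -0.35 for cytosolic ribosomal proteins.

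In ssy1T9 the same 9 permease genes fell. TAT1 and BAP3 were 8.73-fold and 8.63-fold lower than in wt, BAP2 6.48-fold, GNP1 4.63-fold, PTR2 4.43-fold and TAT2 3.61-fold lower. MUP1 fell by 1.57 and DIP5 by 1.24 on the log2 scale. AGP1 fell least, by 0.33 (SE 0.08, adjusted p = 0.00366). Its call held under 10 of 15 alternatives; it was at -0.27 without T9/wt array 1 (adjusted p = 0.115) and at -0.15 without centring (adjusted p = 0.223). PUT1 was 16.2-fold and DAL3 7.94-fold higher than in wt, GAP1 11.3-fold higher and CHA1 5.77-fold lower.

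By limma, 1494 genes differed in ssy1T9 against wt, 803 higher and 691 lower, 51 and 28 of them at least 2-fold. Among the called genes 95.2% had one sign on both T9/wt arrays, against 47% of the genes not called. These arrays are part of the fit too, so the agreement is again partly built in. Their correlation across genes as Cy5 over Cy3 was r = -0.67 (Spearman -0.41). Without centring the median of all genes lay at 0.17 and the split was 1838 higher and 176 lower (91.3% higher, against 53.7%). Without T9/wt array 1, 793 genes were called.

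In ssy1T9, 4 lists stood apart with either correlation, each at an adjusted p of 0.0317 with an estimated one. Permeases were lower in 9 of 9 cases, 9 adjusted over the list alone (median -2.15, camera adjusted p = 2.2e-23). Sulphate assimilation and methionine genes were higher in 21 and lower in 1 of 27 cases, 22 and 1 adjusted over the list alone (adjusted p = 4.9e-25), led by MET14 (2.31), MET5 (2.26) and MET10 (2.25). Nitrogen catabolite repressed genes were higher in 15 and lower in 1 of 27 cases, also adjusted over the list alone (adjusted p = 2.4e-12). General stress genes were higher in 17 of 24 cases, 18 higher and 1 lower adjusted over the list alone (adjusted p = 8.6e-14), with PGM2 at 1.55 and DDR2 at 1.27. Branched-chain genes rose in 6 of 12 cases, 6 higher and 1 lower adjusted over the list alone (adjusted p = 2.5e-05; adjusted p = 0.121 with an estimated correlation), with LEU2 at 2.21 and LEU1 at 2.02. Histidine genes rose in 6 of 7 cases and arginine genes in 5 of 8, both also adjusted over the list alone (adjusted p = 2.3e-04 and 8.9e-05; adjusted p = 0.108 and 0.106 with an estimated correlation). In the glutamate, proline and asparagine list 7 of 13 genes rose and 2 fell, also adjusted over the list alone (adjusted p = 8.5e-04; adjusted p = 0.145 with an estimated correlation), with GDH1 at 2.37. Outside these lists GAT1 rose to 2.24.

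Falls in ssy1T9 likewise included glycine cleavage and ribosomal genes. GCV1 fell by 1.85 and GCV2 by 1.10. In their list 8 of 17 serine, glycine and threonine genes fell and 4 rose, 9 and 4 adjusted over the list alone (median -0.24, and -0.07 without centring; adjusted p = 0.00155; adjusted p = 0.184 with an estimated correlation). Cytosolic ribosomal protein genes fell in 108 of 137 cases, 117 adjusted over the list alone (adjusted p = 3.4e-27; adjusted p = 0.182 with an estimated correlation). Their median was -0.35, and -0.18 without centring, with RPL38 at -0.64 and RPP1A at -0.61. Ribosome biogenesis genes fell in 14 of 22 cases, 17 adjusted over the list alone (adjusted p = 3.3e-07; adjusted p = 0.0535 with an estimated correlation), with a median of -0.27, and of -0.10 without centring. OPT1 fell by 1.89 and PHO3 by 1.68. Of the 8 auxotrophic marker genes 5 were higher and 1 lower, also adjusted over the list alone (adjusted p = 1.2e-05; adjusted p = 0.184 with an estimated correlation), and URA3 was at -0.04 (adjusted p = 0.772).

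Within the sensor pathway itself, STP2 rose to 0.77 in ssy1KO and 0.69 in ssy1T9 (SE 0.08 for both, adjusted p = 5.8e-08 and 3.8e-07). PTR3, STP1 and DAL81 also rose in both, to 0.38, 0.30 and 0.26 in ssy1KO and to 0.37, 0.27 and 0.24 in ssy1T9, but these calls did not hold with every array left out. PTR3 lost its call in ssy1KO, at an unchanged 0.38, without KO/wt array 1 (adjusted p = 0.078) and in ssy1T9, at 0.25, without T9/wt array 1 (adjusted p = 0.169). STP1 lost it in ssy1KO without T9/KO array 1 (adjusted p = 0.0523) and in ssy1T9 without T9/wt array 1 or 2 (adjusted p = 0.193 and 0.234). DAL81 lost it in ssy1KO without T9/wt array 1, KO/wt array 2 or T9/KO array 1 (adjusted p = 0.1, 0.182 and 0.0818), and in ssy1T9 without T9/wt array 1 or 2 or KO/wt array 2 (adjusted p = 0.346, 0.0513 and 0.0619). SSY5, encoding the protease of the sensor, was at -0.17 in ssy1KO and -0.16 in ssy1T9 and did not pass (adjusted p = 0.127 and 0.133). GRR1, YCK1, YCK2, ASI1, ASI2 and ASI3 did not pass either, at values from -0.07 (GRR1) to 0.24 (ASI3) in ssy1KO and from -0.04 (YCK2) to 0.18 (ASI3) in ssy1T9. As a list of 12, with SSY1 included, 4 genes rose and 1 fell in ssy1KO, 5 and 1 adjusted over the list alone (adjusted p = 0.408). In ssy1T9 5 rose, also adjusted over the list alone (adjusted p = 0.0301; adjusted p = 0.184 with an estimated correlation); without T9/wt array 1 or 2 the list did not pass (adjusted p = 0.167 and 0.0841), with a median of 0.10 without array 1.

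The effects of both alleles were alike across genes. Of the genes called in both mutants, 637 were higher in both and 493 lower in both. Independent lists as long as the full lists of calls, 789 and 803 higher and 597 and 691 lower, would share 111 and 72.2 genes. Simulated strains without effects, measured in the same loop, shared 0.02 calls per direction on average, a count near 0 by construction because nothing was changed. Lists of those full lengths taken from the simulated strains by smallest p shared 299 and 219. The simulated noise was independent between arrays, so likeness from error in a shared wt culture is not part of these values. The 1 gene called in opposite directions was SSY1. Across genes, which are not independent replicates, the fitted fold changes correlated with r = 0.944 and a covariance of 0.0865. The simulated strains gave r = 0.501 and a covariance of 0.00339. From the arrays of each mutant with wt alone, which share no array, r was 0.869 and the covariance 0.0828. Setting arrays of opposite dye orientation against each other gave r = 0.635 and r = 0.56. Arrays of like orientation gave r = 0.871 and r = 0.738. All values share the wt strain, so part of the likeness may come from it.

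**Figure D3:**
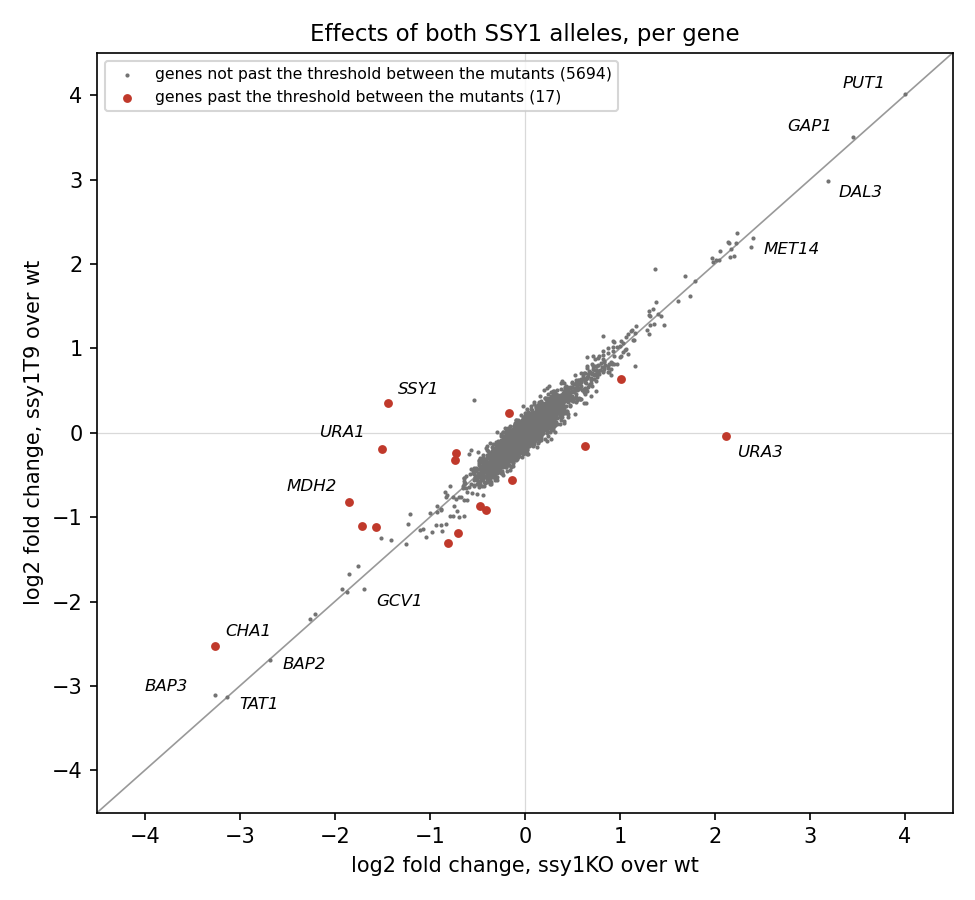
Log2 fold change over wt in ssy1T9 against that in ssy1KO for 5711 genes, with the line of equality. Red points are the 17 genes past the threshold between the mutants, such as SSY1 and URA3, and grey points all others; the fold changes correlate with r = 0.944 across genes.

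Between ssy1KO and ssy1T9, few genes differed. SSY1 lay lower in ssy1KO (log2 -1.80, SE 0.09, adjusted p = 2.4e-13). URA3, encoding orotidine phosphate decarboxylase of uracil synthesis and a common selection marker, was 4.46-fold higher there (log2 2.16, SE 0.08, adjusted p = 9.7e-16). TIM9, which encodes a mitochondrial import chaperone and is the immediate neighbour of URA3 in the R64 reference, was 1.73-fold higher (SE 0.08, adjusted p = 8.4e-07). URA1, encoding dihydroorotate dehydrogenase, lay at -1.31, the uridine permease gene FUI1 at -0.61, MDH2 at -1.03 and CHA1 at -0.73 in ssy1KO over ssy1T9. Among the permease genes controlled by the sensor only AGP1 passed, at -0.41 (adjusted p = 0.0139).

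By limma 17 of 5711 genes differed in ssy1KO against ssy1T9, 8 higher and 9 lower in ssy1KO. On both T9/KO arrays, which are part of that fit, 17 of 17 had one sign, against 49.9% of the genes not called. Across all genes these arrays correlated with r = -0.03 as Cy5 over Cy3. An unadjusted p under 0.05 was seen for 310 genes. With no true difference a share of 0.05 of the tested genes is due by chance, so the 310 do not count as further differences. COS12, HEM3 and PHO89 were the other genes of the naming rule, at 0.50, 0.49 and 0.49. URA4 (-0.48), SED1 (-0.45), YRO2 (-0.40), HXT2 (0.42), HAC1 (0.40) and SRL3 (0.38) complete the 17; URA4, SED1, YRO2, HAC1 and SRL3 were chosen after their values were seen. With each array left out in turn, 7 genes passed every time (SSY1, URA3, TIM9, URA1, MDH2, FUI1 and CHA1) and 10 lost the call at least once. Under all 15 alternatives 5 held: CHA1, whose dye effect also passed (0.27, adjusted p = 0.0105), lost its call without the dye intercept (adjusted p = 0.158; its others ran from 1.5e-12 without T9/wt array 2 to 0.0478 with arrays scaled to one spread). FUI1 lost its call in the test against a 1.2-fold change (adjusted p = 0.0636; its others ran from 1.0e-07 without T9/wt array 2 to 0.0228 without the dye intercept). All 10 lost it without KO/wt array 1 (adjusted p from 0.0516 for HEM3 to 0.502 for SRL3) and again without T9/KO array 1 (from 0.097 for URA4 to 0.998 for HAC1), fits that called 7 genes each. Without T9/wt array 1, 11 genes were called, and AGP1, COS12, HXT2, HAC1, SRL3 and YRO2 lost the call. AGP1, HAC1 and SRL3 also lost their calls without T9/KO array 2 (adjusted p = 0.314, 0.0569 and 0.0594), with AGP1 at -0.31, and SRL3 without T9/wt array 2 (adjusted p = 0.0593). HEM3, HXT2, HAC1 and SRL3 lost theirs without KO/wt array 2 as well (adjusted p = 0.0629, 0.0921, 0.252 and 0.177). For the typical gene, the 95% interval of a difference reached 0.166 to either side on the log2 scale.

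**Figure D4:**
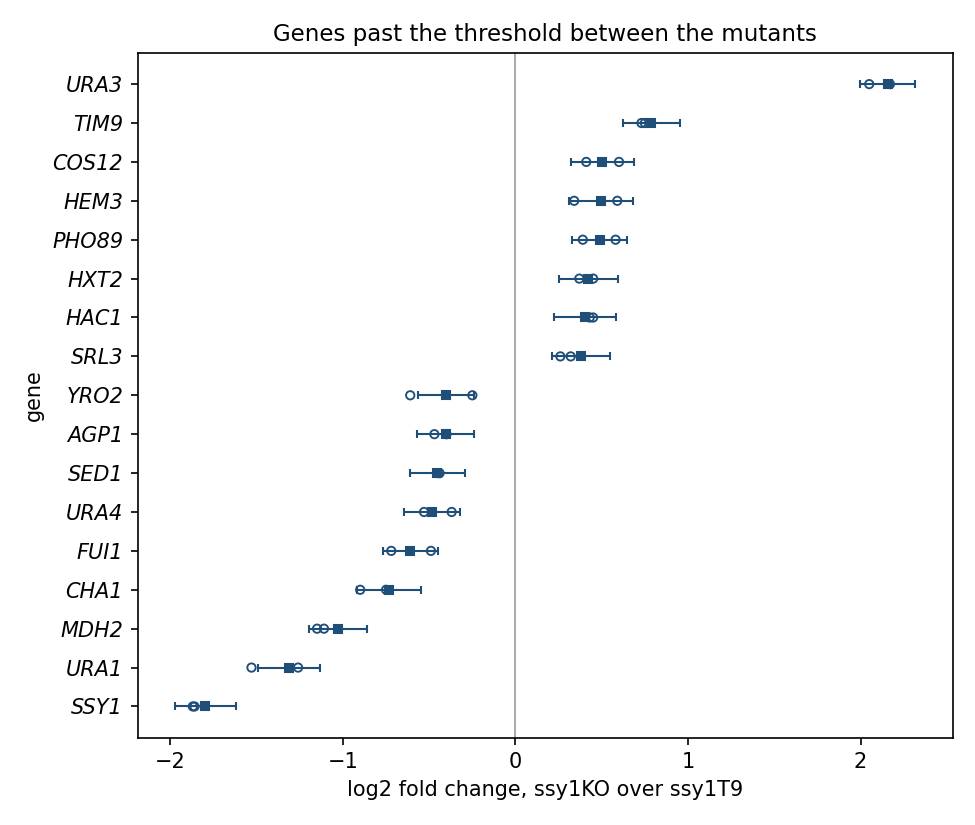
Log2 fold change of ssy1KO over ssy1T9 for the 17 genes past the threshold. Squares are fitted values over 6 arrays with 95% confidence intervals and open circles the 2 arrays of the pair; values run from -1.80 for SSY1 to 2.16 for URA3.

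As a list, the 9 permeases lay slightly lower in ssy1KO than in ssy1T9. Of the 9, 8 were below 0, with a median of -0.07 and 1 called, 2 adjusted over the list alone (camera adjusted p = 6.4e-04). That call was lost with an estimated correlation (adjusted p = 0.298), with arrays scaled to one spread (adjusted p = 0.161) and without T9/KO array 2 (adjusted p = 0.0504), and without T9/wt array 2 the median was -0.12. General stress genes also lay lower (median -0.07, adjusted p = 0.00199; adjusted p = 0.298 with an estimated correlation). By limma 0 of 24 were called and 0 adjusted over the list alone, and 3 had an unadjusted p under 0.05. Phosphate genes lay higher (median 0.10, adjusted p = 0.0025; adjusted p = 0.298 with an estimated correlation), with 1 of 13 called and 5 adjusted over the list alone; without T9/KO array 1 the adjusted p was 0.0553. Iron genes lay higher too (median 0.10, adjusted p = 0.00193; adjusted p = 0.298 with an estimated correlation), with 0 of 16 called by limma, 4 adjusted over the list alone and 5 with an unadjusted p under 0.05; without KO/wt array 2 the median was 0.05.

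Cytosolic and mitochondrial ribosomal protein genes and auxotrophic markers, with URA3, also passed the preset test between the mutants (adjusted p = 0.00199, 0.00547 and 0.00159; adjusted p = 0.656, 0.613 and 0.613 with an estimated correlation). Their medians were 0.04, 0.06 and 0.07. Called over all genes were 0, 0 and 1 by limma, 0, 1 and 1 adjusted over the list alone, and 17, 2 and 2 had an unadjusted p under 0.05. Cytosolic ribosomal protein genes did not pass without T9/wt array 2 or KO/wt array 2 (adjusted p = 0.966 and 0.691), from the own 2 arrays of the pair (adjusted p = 0.799) or with arrays scaled to one spread (adjusted p = 0.337). Mitochondrial ones did not without T9/wt array 2 or T9/KO array 2 (adjusted p = 0.117 and 0.322) or from the pair's own arrays (adjusted p = 0.0812). Nor did the markers without KO/wt array 2, from the pair's own arrays or with arrays scaled to one spread (adjusted p = 0.0677, 0.0704 and 0.233). Cytosolic medians were 0.01 without T9/wt array 2 or KO/wt array 2, 0.12 without T9/KO array 1 and 0.07 without T9/wt array 1. The mitochondrial median was 0.03 without T9/KO array 2, and the marker median 0.03 without KO/wt array 2, 0.12 without T9/KO array 2 and 0.04 without T9/wt array 2. Of the 28 lists 0 passed fry between the mutants and 8 had an unadjusted p under 0.05, while camera with an estimated correlation passed 0, with 4 under 0.05 unadjusted, and 5 passed fry's mixed test for change in either direction.

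For the remaining lists, values are given for ssy1KO and then ssy1T9. Of 9 lysine genes 5 and 6 rose and 1 fell in each, 6 and 1 in both adjusted over the list alone (adjusted p = 0.0212 and 0.00616; adjusted p = 0.227 and 0.184 with an estimated correlation). LYS1, encoding saccharopine dehydrogenase, was at 0.77 and 0.80, and without T9/wt array 2 the list's adjusted p in ssy1KO was 0.0509. Of 15 aromatic genes 7 and 8 rose and 1 and 3 fell, 9 and 8 higher and 2 and 3 lower adjusted over the list alone (adjusted p = 0.036 and 0.0938; adjusted p = 0.2 and 0.226 with an estimated correlation). In ssy1KO the aromatic list did not pass without T9/wt array 1 or 2 or T9/KO array 2 (adjusted p = 0.051, 0.119 and 0.0584), nor without centring or from the own 2 arrays of its pair (adjusted p = 0.0753 and 0.0708). Of 12 purine genes 6 fell in each and 1 rose in ssy1KO, with the same counts adjusted over the list alone (adjusted p = 0.00393 and 7.5e-04; adjusted p = 0.224 and 0.184 with an estimated correlation). Purine medians were -0.18 and -0.23, and -0.03 and -0.06 without centring, with ADE1 at -0.61 and -0.70. Of 11 other amino acid permeases 2 rose in each, and 4 and 5 fell. Adjusted over the list alone 3 and 2 were higher and 4 and 5 lower. The list did not pass camera (adjusted p = 0.13 and 0.146) but passed fry (adjusted p = 0.00456 and 0.00543). Without centring it passed camera (adjusted p = 0.0341 and 0.0367), and its median turned from -0.105 and -0.08 to 0.053 and 0.092. The arginine permease gene CAN1 was at 0.85 and 0.80 and OPT2 at -0.88 and -0.90.

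Of 16 iron genes 5 and 6 fell, with 1 and 0 higher and 5 and 6 lower adjusted over the list alone (adjusted p = 0.0322 and 7.3e-04; adjusted p = 0.2 and 0.108 with an estimated correlation). The siderophore transporter gene SIT1 was at -1.07 and -1.15. Without centring the iron list's median turned from -0.07 and -0.14 to 0.09 and 0.04, and in ssy1KO the list did not pass without T9/wt array 2 or T9/KO array 1 (adjusted p = 0.0648 and 0.051), with arrays scaled to one spread or from its own 2 arrays (adjusted p = 0.0543 and 0.0631); without T9/wt array 1 its median was -0.10. Of 67 mitochondrial ribosomal protein genes 8 and 11 were lower and 3 and 2 higher, 6 and 10 lower and 2 and 2 higher adjusted over the list alone (adjusted p = 0.0278 and 4.4e-04; adjusted p = 0.38 and 0.213 with an estimated correlation). Their median turned from -0.08 and -0.13 to 0.07 and 0.04 without centring, and in ssy1KO the list did not pass without T9/wt array 2 or T9/KO array 1 (adjusted p = 0.181 and 0.0585), nor without centring (adjusted p = 0.0604). Of 20 glycolysis and fermentation genes 4 and 3 were higher, 4 and 2 adjusted over the list alone, and the list passed in ssy1T9 (adjusted p = 0.118 and 0.00646; adjusted p = 0.528 and 0.29 with an estimated correlation). Its median there was 0.11, and 0.20, 0.05 and 0.07 without T9/wt array 2, KO/wt array 2 and T9/KO array 1; from its own 2 arrays the list did not pass (adjusted p = 0.0502). The glucokinase gene GLK1 was at 1.31 and 1.28 and HXK1 at 0.94 and 0.82.

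Hexose transporters (adjusted p = 0.693 and 0.762), respiration (0.466 and 0.976) and phosphate (0.958 and 0.269) did not pass camera as lists. Nor did thiamine and pyridoxine (0.14 and 0.16) or daughter cell separation (0.765 and 0.976). By fry, hexose transporters (adjusted p = 0.0122 and 0.0349), thiamine and pyridoxine (0.0218 and 0.0225) and phosphate in ssy1T9 (0.00725) did pass. Respiration, daughter cell separation and phosphate in ssy1KO did not pass fry either. Called genes of these lists, in the order first given, numbered 3 and 4 of 12, 5 and 3 of 36, 3 and 4 of 13, 5 and 4 of 19, and 1 and 0 of 9. Adjusted over the list alone they were 3 and 4, 2 and 2, 3 and 4, 5 and 4, and 0 and 0; of the daughter cell genes 1 and 0 had an unadjusted p under 0.05. PHO89, encoding a phosphate transporter, was at -0.70 and -1.19. Genes of cell type were included as checks of strain identity. Of 7 MATa-specific genes 1 and 0 were called by limma, 0 and 0 adjusted over the list alone, and 1 and 2 had an unadjusted p under 0.05 (list adjusted p = 0.958 and 0.983). Of 11 haploid-specific genes 0 and 0 were called by limma, also adjusted over the list alone, and 2 and 1 had an unadjusted p under 0.05 (list adjusted p = 0.914 and 0.805). Of 4 MATalpha-specific genes 3 and 2 were lower, 3 and 3 adjusted over the list alone (adjusted p = 0.0322 and 0.0806; adjusted p = 0.239 and 0.29 with an estimated correlation), with SAG1, encoding alpha-agglutinin, at -0.55 and -0.48. That list did not pass in ssy1KO without KO/wt array 1, T9/wt array 2 or T9/KO array 2 (adjusted p = 0.164, 0.0748 and 0.0504), with a median of -0.41 in all and -0.23 without the first of these. Nor did it pass without the dye intercept or from its own 2 arrays (adjusted p = 0.11 and 0.0778). Median and mean differed in sign for phosphate, MATa-specific and daughter cell genes in ssy1KO and for respiration in ssy1T9, and between the mutants for the sensor, nitrogen catabolite repressed, other permease, hexose transporter and MATa-specific lists. None of these 9 passed; the test took the sign of the median for phosphate and MATa-specific genes in ssy1KO and respiration in ssy1T9, and that of the mean for the others.

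The dye effect, a response to dye orientation whatever the strains, was called by limma for 448 genes, 250 higher and 198 lower in Cy5. It was called for 57 without KO/wt array 1, 97 without T9/wt array 1, 200 without KO/wt array 2, 199 without T9/KO array 1 and 687 without T9/KO array 2.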

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

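All tests of explanations in this part were chosen after the results were seen, except that of the genes further from URA3, whose bound was set before their values were looked at.

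The 17 genes that differed between ssy1KO and ssy1T9 by limma stand out because the effects of the alleles differ there in a direct test. In ssy1KO over ssy1T9 the log2 values were URA3 2.16, TIM9 0.79, COS12 0.50, HEM3 0.49, PHO89 0.49, HXT2 0.42, HAC1 0.40 and SRL3 0.38 for the higher genes. They were SSY1 -1.80, URA1 -1.31, MDH2 -1.03, CHA1 -0.73, FUI1 -0.61, URA4 -0.48, SED1 -0.45, AGP1 -0.41 and YRO2 -0.40 for the lower ones. Among the 1628 rows with no gene name here, which no comparison uses, row 5880 lay at 2.54 and row 6516 at 1.10 in ssy1KO over wt, and at 2.62 and 1.18 in ssy1T9 over wt.

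In the first pattern URA3 is higher and URA1, URA4 and FUI1 are lower in ssy1KO than in ssy1T9. All 4 genes had one sign on both arrays of the pair. The difference was at least 4.75 times the dye effect for the 3 genes with a dye effect to compare. However, the 4 genes were chosen from calls of a fit that holds a dye intercept, and 17 of 17 such calls had one sign. The check could therefore hardly fail and decides nothing further about a gene-specific dye effect. An extra copy of the wider region is argued against, if the values are log2, on which the bound rests. The 10 measured genes beyond the immediate neighbours had a median of 0.10 (SD 0.09) where 0.58 was required. A shorter extra copy was not tested, and the neighbours TIM9 (0.79) and GEA2 (0.30, adjusted p = 0.192) lay higher. A URA3 marker gene carried by ssy1KO alone remains a candidate explanation, with URA3 at 2.16 over ssy1T9 and 2.12 over wt and at -0.04 in ssy1T9 over wt. If so, the pyrimidine genes and perhaps TIM9 may differ between the mutants through the marker and not through SSY1, which these arrays did not test. A URA3 difference cannot account for falls also seen in ssy1T9. By limma FUI1 lay at -1.105 in ssy1T9 over wt (adjusted p = 3.8e-11), against -1.715 in ssy1KO. URA4 lay at -0.235 (adjusted p = 0.0278), against -0.72 in ssy1KO. URA1 did not pass in ssy1T9 (-0.197, adjusted p = 0.0982) and lay at -1.508 in ssy1KO.

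In the second pattern 637 genes are higher and 493 lower in both mutants than in wt. Gene-specific dye effects as the whole source are argued against. One mutant's effect on one dye orientation still correlated across genes with the other's on the opposite orientation, at r = 0.56 or more. By rank (Spearman) the same arrays gave weaker values, -0.35 and -0.31 as Cy5 over Cy3, where a shared effect has a negative sign. Arrays of like orientation gave r = 0.871 and 0.738, where each single array still holds its dye effect. A dye effect equal on all arrays cancels from the fitted values, since each pair has both orientations. The fitted r was therefore 0.944 with and without the dye intercept. Dye effects that differ between arrays were not tested. The state of the wt culture remains open and cannot be told apart from SSY1: general stress genes lay at a median of 0.52 or more in both mutants, which slower growth of the mutants or a different wt culture could both give, and the labels name no second wt culture. A wt strain that lacks LEU2 and MET17 also remains open: LEU2 exceeded the next highest branched-chain gene by only 0.40 in ssy1KO and MET17 lay below MET14, yet how much signal a deleted gene leaves on these arrays was not measured. An effect of both SSY1 alleles is the biological explanation the groups give; it stays untested beside these, and the labels do not describe what ssy1T9 does to the sensor.

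In the third pattern the permeases controlled by the sensor lie slightly lower in ssy1KO than in ssy1T9. A difference in ratio scale between the arrays of both mutants stays open: genes called higher in both had a median difference of 0, yet with arrays scaled to one spread the permease median was -0.03 and the list did not pass (adjusted p = 0.161). Whether AGP1 and DIP5 alone carry it is open as well, the 7 others having a median of -0.063 with 6 below 0 (camera p = 0.0198 with the preset and 0.198 with an estimated correlation). Sensor activity left in ssy1T9, the biological candidate, would give the sign of the median over 9 permeases, -0.068, but with an estimated correlation the list did not pass (adjusted p = 0.298).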

How the results depend on the processing

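The alternatives were chosen before the data were examined, except the centring of 16 runs of consecutive rows apart, chosen after seeing the data. Against 1386, 1494 and 17 genes called in ssy1KO against wt, ssy1T9 against wt and ssy1KO against ssy1T9, dropping the dye intercept gave 740, 812 and 6, each comparison from its own 2 arrays 882, 859 and 7, and the test against a 1.2-fold change 265, 283 and 6; scaling arrays to one spread gave 883 for ssy1KO against wt. The test against 1.2-fold asks for more by construction. Dropping the dye intercept left the fold changes unchanged, such as -1.442 for SSY1 in ssy1KO over wt. Its lower counts therefore come from the error estimate, in which the dye effect then stays. A comparison from its own 2 arrays rests on fewer arrays by construction, and how much that cost was not tested. For scaling the cause was not tested. With an array left out the counts ran from 626 to 1513, from 793 to 1457 and from 7 to 19. The dye effect, called for 448 genes, was called for 5586 without centring, where the array medians count as dye effect by construction, for 236 from the own arrays of each pair, and for 57 to 687 with an array left out. With an estimated correlation, a test on 3 degrees of freedom, 4, 4 and 0 of the 28 lists passed, against 18, 18 and 7. With fry 19, 23 and 0 passed. SSY1 in ssy1T9 over wt was 0.29 from its own 2 arrays (adjusted p = 0.0896) and 0.36 in the test against 1.2-fold (adjusted p = 1), and neither passed; under its other alternatives the adjusted p ran from 8.5e-05 to 0.0488. The likeness of both effects stayed between 0.919 and 0.946 with an array left out. Of 3450 alternative values of named genes, 3105 kept their call, 345 lost it and 0 reversed. These cover only the 230 pairs of a named gene and a comparison that had passed the threshold. Dropping the dye intercept, averaging dye-swapped arrays, robust eBayes and the 1.2-fold test leave the fold change unchanged and could reverse none. The absence of reversals was therefore largely fixed in advance. Filters on missing values could change nothing, because no value is missing. No paired analysis was possible because the labels give no replicate numbers that link arrays of different pairs of strains; each ratio itself pairs 2 strains, and groups of 2 arrays allow no count of other splits. Signal over background limits what faint spots can show and was not analysed here.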

Other observations

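The gene groups in this part were chosen after the data had been examined and share members with the lists above, so their tests are descriptions of these arrays. Camera p-values of the groups were adjusted over these groups alone within a comparison, not together with the lists fixed beforehand. With fewer tests the adjustment is milder, so these values are not equal in weight to similar adjusted p-values of those lists. Genes of glycogen and trehalose metabolism, the storage carbohydrates of yeast, were higher in 11 of 18 cases in ssy1KO and in 15 of 18 in ssy1T9, with 0 lower (camera adjusted p = 3.2e-10 and 1.6e-12; adjusted p = 0.0337 and 0.0297 with an estimated correlation). The glycogen synthase gene GSY1 was at 1.68 and 1.85, the branching enzyme gene GLC3 at 0.88 and 1.01 and the glycogen phosphorylase gene GPH1 at 0.93 and 1.09; GPH1, PGM2, TPS1, TPS2, TSL1 and GSY2 are also in the general stress list. Genes of vacuolar hydrolases were higher in 7 of 10 cases in both mutants (adjusted p = 2.5e-05 and 9.2e-06; adjusted p = 0.0337 and 0.0297 with an estimated correlation), led by the aminopeptidase gene APE1 at 1.40 and 1.41 and the protease gene PRB1 at 0.82 and 0.87, the latter also counted among nitrogen catabolite repressed genes.

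Of 5 genes of GATA factors and their regulator, 4 were higher in both mutants (adjusted p = 1.4e-05 and 5.0e-06; adjusted p = 0.0337 and 0.0297 with an estimated correlation): the activator genes GAT1 (2.22 and 2.24) and GLN3 (0.50 and 0.49) and the repressor genes DAL80 (2.20 and 2.10) and GZF3 (0.32 and 0.35), while URE2 was at -0.11 and -0.02 and did not pass. Within the nitrogen catabolite repressed list the response was uneven: the ammonium permease gene MEP1 was at 1.61 and 1.56 and MEP2 at -0.07 and 0.02, and the allantoin genes DAL3 and DCG1 rose while DAL1, DAL2, DAL4, DAL5 and DAL7 did not pass in either mutant. In phospholipid synthesis, which did not pass as a list (adjusted p = 0.212 and 0.496), CHO2, encoding the first methyltransferase of phosphatidylcholine synthesis, was at -1.41 and -1.27 and the phosphatidylserine synthase gene CHO1 at -0.48 and -0.40. Of 15 genes of pyrimidine synthesis and uptake 5 were lower in each mutant and 1, URA3, was higher in ssy1KO (adjusted p = 0.004 and 0.0135; adjusted p = 0.0642 and 0.0904 with an estimated correlation).

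Between the mutants, glycogen and trehalose genes lay lower in ssy1KO than in ssy1T9, with a median of -0.08 and 16 of 18 below 0 (camera adjusted p = 0.00343; adjusted p = 0.22 with an estimated correlation). In the pyrimidine list URA3 was higher and URA1, URA4 and FUI1 were lower (adjusted p = 0.0108; adjusted p = 0.22 with an estimated correlation). Phospholipid, vacuolar hydrolase and GATA factor genes did not pass there (adjusted p = 0.17, 0.316 and 0.701).

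Of the 1628 rows with no gene name here, 41 were called in ssy1KO against wt, 68 in ssy1T9 against wt and 0 between the mutants by limma. Between the mutants 77 had an unadjusted p under 0.05. A share of 0.05 of the rows is due by chance with no true difference, so the 77 do not count as differences.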
